A study of Mus musculus with 6 samples.

How the data were processed

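Bulk RNA sequencing was done on primary cardiomyocytes isolated from neonatal mouse hearts. The cells had received an adenovirus of serotype 5 in which the cardiac troponin T (cTNT) promoter drives expression in cardiomyocytes. The virus carried either HMGB2 or no insert, called the vector here. There were 6 libraries, 3 with the vector and 3 with HMGB2. Total RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V5 kit, per the labels' protocols. The strand setting, the amount of virus, the time of collection and the source of the HMGB2 coding sequence are not given in the sources used here.

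The submitters' processing notes name FastQC 0.10.1, HISAT2 2.2.1, HTSeq 0.6.1, StringTie 1.3.3b and the genome build mm10, without saying what each tool was used for. The deposited table of the whole series holds whole-number counts per Ensembl gene, which are raw and not normalized, with 1 column per library and 56691 gene rows. A second table deposited by the authors holds FPKM values (fragment counts scaled by gene length and library total) for the same genes and libraries. For all 2159 genes with an FPKM of at least 20 in all 6 libraries, the gene length implied by the count, the FPKM and the library total varied between libraries by under 1% (coefficient of variation). The FPKM values are therefore the same counts rescaled, and they were used only as an alternative. All columns of per-sample values were used. The columns carry short names that were matched to the samples through the group abbreviation and the replicate number, and the abbreviations are not spelled out in the labels.

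Of the gene rows, 52073 have an identifier in GENCODE M21, the annotation of GRCm38 used here, and 1472 of these have the same start and end in the table as in that annotation. The positions in the tables were therefore not printed. Positions in the text are from GENCODE M21 on GRCm38, found through the Ensembl identifier. Gene symbols are those in the tables, where 2639 rows have none.

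The totals were 12498215, 13911926 and 14101385 counts for vector 1, 2 and 3, and 16618365, 14497676 and 16269222 counts for HMGB2 1, 2 and 3. Mitochondrially encoded genes took between 4.96% and 5.37% of the counts of a library, and factors of the trimmed mean of M values (TMM) lay between 0.986 and 1.016. No pair of libraries of a group agreed within sampling noise, with a chi-square per degree of freedom of at least 1.995 over genes with a mean count of 20 or more. Each library was counted as 1 sample. The labels do not say whether replicates are separate cultures, isolations or animals, so the p-values measure the spread between these samples, which may be technical.

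Genes were tested with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr (minimum count 10, minimum total count 15), which left 15429 genes, library sizes were scaled by TMM, and a robust quasi-likelihood fit with the group as the only term gave an F-test per gene. The p-values were adjusted over all genes tested by Benjamini-Hochberg, and an adjusted p under 0.05 counted as past the threshold, with no fold threshold. Standard errors (SE) of log2 fold changes were taken as the absolute log2 fold change over the square root of F. Expression is given as CPM, the count of a gene scaled to a common library size, on TMM-scaled library sizes. A permutation of 3 against 3 samples cannot give a two-sided p under 0.1, so no exact test of a single gene is given.

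The 29 gene lists were fixed before the data were examined, as were the tests and the rule for named genes. Lists were tested with camera (limma 3.58.1) on the edgeR object with a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the 28 lists with tested members. Beside it stand camera with a correlation estimated from the data and fry. With fry's directional test, 19 lists had an adjusted p under 0.05, and fry does not compare a list with other genes. Hmgb2 is in no list. The named genes are Hmgb2, Hmgb1, Hmgb3 and Mta2, then the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 1 on the log2 CPM scale, with the groups fully separated and with a symbol that is not a clone or predicted-gene name. To these come, for each list, up to 4 members past the threshold with the smallest p, or up to 2 with the highest mean where fewer than 2 passed. Some genes that the rule takes are not reported here. A gene outside this rule is said to have been chosen after its values were seen. There were 5 further lists, chosen after the data were seen, which are described without a list test.

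On simulated counts with the means, dispersions and library sizes of the HMGB2 and vector libraries, 200 genes with a mean count of at least 20 were changed among 15182 that entered the fit. The edgeR test recovered 74.6% of 67 genes changed by 1.5-fold, 88.1% of 67 changed by 2-fold and 100% of 66 changed by 4-fold, and it called 16 unchanged genes among 191 calls. With no gene changed it called 1 gene. With 12 members of the citric acid cycle list raised by 2-fold, camera called that list and no other, and with no gene changed it called 0 lists. Genes were simulated independently of each other, so this does not test the preset correlation of 0.01. The correlation estimated from the real data was 0.531 for the citric acid cycle list. Of the 14 lists called with the preset correlation, 2 were called with an estimated one.

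Transcripts of the named genes and of the added chaperone list were searched against the longest transcript of each GENCODE M21 gene with blastn 2.17.0 (identity of at least 95%, alignments of at least 100 nt). Of 122 named genes, 9 had such a copy over at least 50% of the transcript among the tested genes (among them Bnip3, Hspa1a, Hspa1b, Ldhb, Oas1g, Tagln, mt-Atp6 and mt-Nd4), and their counts are uncertain because the handling of reads that match several genes is not given in the sources used here. The exons of 17 named genes overlap those of a tested gene on the other strand (among them Atp2a2, Atp5a1, Ccn2, Ccne2, Crim1, Eng, G6pdx, Gja5, Hk1, Hmgb1, Lig1, Mylk, Pfkm, Pln, Rbl2 and Tagln), whose reads cannot be told apart without a stated strand setting. Hmgb1, Hmgb2, Hmgb3, Pln and the chaperones Dnaja1 and Hspe1 have tested copies over 20% to 50% of their transcripts, and their counts are uncertain too.

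The alternatives fixed beforehand were size factors of the DESeq2 type, library totals alone, TMM without mitochondrially encoded genes and Hmgb2, no count filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) with and without a filter and on log2(FPKM + 0.1), the replicate number as a block, each library left out in turn, a log2 fold change of at least 1, and a test against a fold of 1.2. Alternatives added after the data were seen were leaving out vector 1 and HMGB2 3 together, a surrogate variable (sva 3.50.0) as a covariate, and a correction of each library for transcript length and GC content by loess with a span of 0.3, for which 99.1% of tested genes had a transcript in GENCODE M21.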

Results

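Gene expression was measured by RNA sequencing in primary cardiomyocytes of neonatal mice that received an adenovirus with HMGB2 under the cTNT promoter or the same virus without an insert. HMGB2 is a chromatin-associated high mobility group protein that bends DNA. The series title names cardiomyocyte proliferation, MTA2 (a subunit of the NuRD chromatin remodelling complex) and metabolism, and the comparison of 3 HMGB2 with 3 vector libraries asks which transcripts differ between the groups. Between 12498215 (vector 1) and 16618365 counts (HMGB2 1) per library were assigned to genes, and 15429 genes were tested.

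On the first principal component of the 500 most variable genes, which held 77.4% of their variance, the 3 HMGB2 libraries (19.8 to 21.3) lay apart from the 3 vector libraries (-22.7 to -19.2). Correlations of log2 CPM were 0.984 to 0.993 within groups and 0.966 to 0.974 between groups. The second component held 14.3% and set vector 1 (14.2) and HMGB2 3 (10.6) apart from the other libraries (-8.47 to -4.37). In both of these libraries the deviation from the rest of their group was correlated across genes with transcript length (Spearman's rho -0.48 for vector 1 and -0.45 for HMGB2 3, over 15288 genes, which are not independent replicates). The difference between HMGB2 and vector had a rho of 0.0091 with length and of 0.0061 with GC content.

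Hmgb2 (ENSMUSG00000054717, GRCm38 chromosome 8, 57511907 to 57515999) was 4.33-fold higher with the HMGB2 virus, at 184 ± 10.9 CPM against 42.6 ± 5.59 CPM with the vector (SD, n = 3 each). The log2 fold change was 2.11 (SE 0.10, edgeR adjusted p = 1.89e-06), and the 3 HMGB2 libraries held 175, 196 and 182 CPM against 46.8, 44.8 and 36.3 CPM in the vector libraries. Transcripts of the virus and of the chromosomal gene are not separated in these counts. Part of the Hmgb2 transcript (24.1%) is 99.7% identical to Gm4739, which was 8.37-fold higher with HMGB2 (7.14 ± 0.891 against 59.8 ± 4.24 CPM), and the copy Gm13237 had a log2 fold change of 2.54. Reads of Hmgb2 and of these copies may be counted for each other, so the 4.33-fold value is uncertain. Of its family, Hmgb1 had a log2 fold change of -0.27 that did not pass the threshold (edgeR adjusted p = 0.106) but did in 3 of 20 alternatives, and its exons overlap those of Uspl1 on the other strand. Hmgb3 fell by 0.47 on the log2 scale (SE 0.14, edgeR adjusted p = 0.0369), a call that was lost without vector 1 (adjusted p = 0.0575), vector 2 (0.0551), HMGB2 1 (0.142) or HMGB2 3 (0.0777). Its copy Gm6104, 99.5% identical over 34.6% of the transcript, had a log2 fold change of -1.03, and the counts of Hmgb3 are uncertain for shared reads.

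Mta2 (ENSMUSG00000071646, GRCm38 chromosome 19, 8941875 to 8952303) did not rise. It was slightly lower with HMGB2, at 139 ± 1.72 CPM against 160 ± 2.98 CPM, with a log2 fold change of -0.20 (SE 0.06, edgeR adjusted p = 0.0444) and with all 3 HMGB2 libraries below all 3 vector libraries. This call was lost without vector 2 (adjusted p = 0.106), vector 3 (0.132), HMGB2 1 (0.146), HMGB2 2 (0.138) or HMGB2 3 (0.108), and in 12 of 20 alternatives in all. Of the 15 NuRD genes tested, 3 fell (Mta2, Mta1 and Gatad2a, by 0.20 to 0.26 on the log2 scale), 12 did not pass the threshold and none passed when adjusted over the list alone. The median log2 fold change of the list was 0.06 while the direction of the test was down, and the list was not called (camera adjusted p = 0.787). Without vector 2, vector 3, HMGB2 2 or HMGB2 3 the number of NuRD genes that fell was 0, and without HMGB2 1 it was 1. In turn, 2 rose without vector 1, 1 without HMGB2 3, and 4 rose and 6 fell without both of these libraries. Mta1 and Gatad2a lost their calls with adjusted p values up to 0.14 and 0.131, both without HMGB2 2.

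HMGB2 was accompanied by a broad change, with 2224 genes higher and 1662 lower, together 25.2% of the genes tested (edgeR, adjusted p under 0.05). By at least 2-fold, 743 genes rose and 166 fell. All 3 libraries of a group lay above all 3 of the other for 40.5% of tested genes, where chance gives 10%. The median log2 fold change of all tested genes was -0.0022. The number of lower genes depended on the libraries more than that of higher genes, being 973 without vector 2, 866 without HMGB2 1 and 897 without HMGB2 2, and 2986 without vector 1 and HMGB2 3 together.

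Among the genes with the largest rises were those of the interferon response. Thrsp, a regulator of lipogenesis, rose 13.6-fold from 0.446 ± 0.111 to 6.21 ± 0.923 CPM (edgeR adjusted p = 1.27e-05). The antiviral genes Oas2, Oas3, Oas1g and Rsad2 rose 12.9-, 10.6-, 7.90- and 8.05-fold, and Oas1g shares 97.6% identity with Oas1a over most of its transcript. Other large rises were those of Rec8, a meiotic cohesin subunit (12.0-fold), P2rx1, an ATP-gated cation channel (10.8-fold), Ky, needed for muscle maintenance (10.8-fold), and Lgi3 (9.38-fold). The size of such rises depended on the processing. The lowest log2 fold change among the alternatives was 1.19 for Ky, 1.68 for Thrsp, 1.72 for Rec8 and Lgi3, and 2.61 for P2rx1. These genes kept their calls under every alternative.

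The largest falls were those of the inducible HSP70 chaperone genes, which are transcribed by HSF1 under heat and other protein stress. Hspa1b (ENSMUSG00000090877, GRCm38 chromosome 17, 34956436 to 34959238) went from 668 ± 5.55 to 7.90 ± 0.186 CPM, 84.6-fold lower with HMGB2 (log2 fold change -6.40, SE 0.08, edgeR adjusted p = 3.01e-10). Its neighbour Hspa1a went from 267 ± 12.2 to 3.17 ± 0.396 CPM (log2 fold change -6.38, edgeR adjusted p = 1.6e-09). These 2 transcripts are 99.2% identical over most of their length, and their summed counts fell by 6.40 on the log2 scale. Hmox1, the haem oxygenase induced by oxidative stress, was 4.39-fold lower (1451 ± 158 against 330 ± 20.3 CPM), and Xirp2, an actin-binding protein of the intercalated disc, was 5.58-fold lower (414 ± 122 against 74.2 ± 14.96 CPM). Wnt7a (5.76-fold), Irx1 (4.04-fold), Tmem236 (6.49-fold), Npc1l1 (6.13-fold), Fbxw10 (5.35-fold) and Blnk completed the 10 largest falls, none of these 6 above 13.2 CPM in either group. Blnk had a log2 fold change of -4.33, or -3.73 without HMGB2 3, the library with 0 counts of it.

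**Figure D1:**
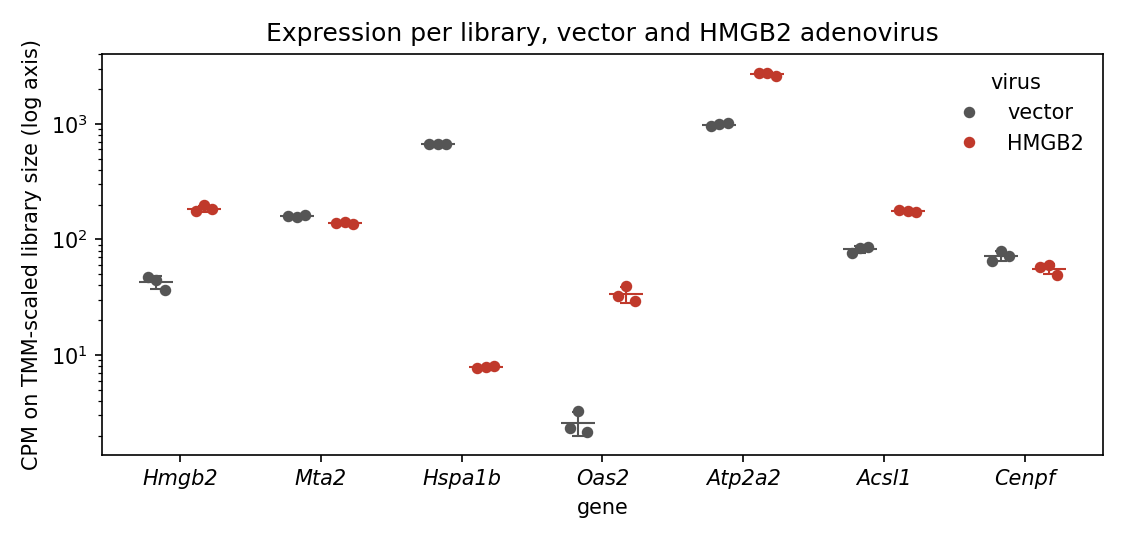
CPM on TMM-scaled library sizes (log axis) of 7 genes in the 3 vector and 3 HMGB2 libraries, with points for libraries and a bar with whiskers for the mean and SD of each group (n = 3). Hspa1b lies at 668 CPM with the vector and 7.90 CPM with HMGB2, Hmgb2, Oas2, Atp2a2 and Acsl1 lie higher with HMGB2, and Mta2 differs little, at 160 and 139 CPM.

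Most genes of DNA replication and mitosis did not pass the threshold. The libraries also hold transcripts of other heart cells, as described below. Cell cycle transcripts can therefore not be assigned to cardiomyocytes, and these values do not measure cardiomyocyte proliferation. Of 30 S phase genes, 6 rose, 2 fell and 22 did not pass the threshold (7 rose and 2 fell when adjusted over the list alone), with a median log2 fold change of 0.12. Against other genes the list was not called (camera adjusted p = 0.168), while fry, which tests a list against no change, called it upward (adjusted p = 0.0346). Among those that rose were the E-type cyclins that drive entry into S phase. Ccne1 rose 2.06-fold from 22.5 ± 1.81 to 46.3 ± 0.277 CPM (edgeR adjusted p = 3.39e-05), and Ccne2 rose 2.11-fold from 33.8 ± 3.45 to 71.4 ± 6.08 CPM (6.9e-05). Tyms, which makes thymidylate, fell by 0.44 on the log2 scale (edgeR adjusted p = 0.0021). The number of S phase genes that rose was 2 without vector 3 or HMGB2 2 and 3 without HMGB2 3, and the number that fell was 1 without vector 1, vector 2, vector 3, HMGB2 1 or HMGB2 2. Of 30 genes of mitosis and cytokinesis, 0 rose, 3 fell (Incenp, Cenpf and Kif23, by 0.25 to 0.38 on the log2 scale) and 27 did not pass, and none passed when adjusted over the list alone. The median was -0.10 and the list was not called (camera adjusted p = 0.0723), though it was without vector 3 (0.0459) and, downward, with fry (adjusted p = 0.00676). At most 1 member fell without vector 2, vector 3, HMGB2 1, HMGB2 2 or HMGB2 3, while 8 fell and 1 rose without vector 1 and HMGB2 3 together. The highest edgeR adjusted p with a library left out was 0.0911 for Incenp (without HMGB2 2), 0.105 for Cenpf and 0.129 for Kif23 (both without vector 2). Mki67 and Top2a, markers of cycling cells chosen here after their values were seen, had log2 fold changes of -0.21 (SE 0.22) and -0.16 (SE 0.07) that did not pass the threshold.

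Among 16 cell cycle inhibitors, 4 rose and 4 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.475). Gadd45b fell 2.01-fold from 18.2 ± 2.38 to 9.03 ± 0.459 CPM and Tob1 rose 1.5-fold. Of 16 p53 target genes, 3 rose and 4 fell, the same counts adjusted over the list alone (camera adjusted p = 0.513), with Ccng1 and Sesn1 1.5- and 1.71-fold higher and Mdm2 and Pmaip1 lower by 0.45 and 0.78 on the log2 scale. Of the inhibitors, 1 rose without vector 2, HMGB2 1 or HMGB2 2, 2 rose without vector 3 or HMGB2 3, and 1 fell without HMGB2 1 and 2 without vector 2, HMGB2 2 or HMGB2 3. Of the p53 targets, 2 fell without HMGB2 2.

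Genes of fatty acid oxidation rose together with HMGB2. Of 25 genes of fatty acid uptake and oxidation, 21 rose, 0 fell and 4 did not pass (23 rose adjusted over the list alone), with a median fold of 1.44 (log2 0.52). Cpt2, the inner carnitine palmitoyltransferase of mitochondria, rose 2.41-fold from 28.5 ± 2.39 to 69.0 ± 3.2 CPM (edgeR adjusted p = 1.08e-05). Acsl1, which activates long-chain fatty acids, rose 2.14-fold (82.1 ± 5.58 to 176 ± 3.18 CPM), the fatty acid transporter Cd36 2.07-fold (72.3 ± 0.875 to 149 ± 2.3 CPM) and the thiolase Acaa2 1.99-fold. The list was called (camera adjusted p = 1.05e-13), but not with an estimated correlation (adjusted p = 0.112). The median of the sarcomere genes was 0.46, and markers of macrophages and endothelial cells had medians of -0.58 and -0.19.

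Among the genes of glycolysis and of the citric acid cycle, 14 of 23 rose in each list. Of 23 glycolysis genes, 14 rose and 0 fell, over all genes and adjusted over the list alone, with a median fold of 1.24 (camera adjusted p = 2.53e-05; adjusted p = 0.268 with an estimated correlation). The leading members were Ldhb, the lactate dehydrogenase subunit abundant in heart, at 2.34-fold (95.6 ± 11.0 to 223 ± 24.6 CPM), Pfkm and Eno3, the muscle forms of phosphofructokinase and enolase, at 2.18- and 2.10-fold, and Hk1 at 1.69-fold. Ldhb is 98.0% identical over most of its transcript to its copy Ldhb-ps, which rose 2.43-fold. The number that rose was 9 without vector 3, HMGB2 1 or HMGB2 2. Of 23 genes of pyruvate oxidation and the citric acid cycle, 14 rose and 0 fell (17 adjusted over the list alone), with a median fold of 1.35 (camera adjusted p = 2.53e-05; adjusted p = 0.379 with an estimated correlation). Idh3a, Sdhc and Dlat rose 1.6-, 1.51- and 1.46-fold. Members were higher by a median of 0.20 on the log2 scale in vector 1 and 0.11 in HMGB2 3 than in the others of their group (0.11 and 0.13 for fatty acid oxidation).

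Of 71 nuclear genes of the respiratory chain and ATP synthase, 17 rose and 0 fell, over all genes and adjusted over the list alone, and 54 did not pass, while 68 had a positive log2 fold change. The median fold was 1.18, Uqcrc2 rose 1.38-fold and Cox6a2, a muscle subunit of cytochrome oxidase, 1.5-fold. The list was called (camera adjusted p = 0.00322), but not with an estimated correlation (adjusted p = 0.772), with fry (0.197) or without HMGB2 3 (0.0709). The list was also higher in the libraries that stood apart on the second component, by a median of 0.37 on the log2 scale in vector 1 and 0.28 in HMGB2 3 over the others of their group. Without vector 1, 51 members rose, without both of these libraries 54, and 4 without vector 2 or vector 3, 6 without HMGB2 1, 10 without HMGB2 2 and 8 without HMGB2 3. Of 13 mitochondrially encoded genes, in contrast, 0 rose and 3 fell, over all genes and adjusted over the list alone, with a median of -0.25. Members chosen after their values were seen show how uneven the list is. The most abundant, mt-Co1 (21993 CPM with the vector), and mt-Nd1 (5647 CPM) had log2 fold changes of -0.03 and 0.006. With the vector, mt-Nd3, mt-Nd4l and mt-Atp8 had only 2.36, 4.51 and 5.26 CPM, and their negative log2 fold changes did not pass the threshold. mt-Cytb went from 6631 ± 200.1 to 5268 ± 36.5 CPM (log2 fold change -0.33, edgeR adjusted p = 0.0048), and the other members that fell were mt-Nd4 and mt-Atp6, which share sequence with near-identical copies outside the list. The list was not called (camera adjusted p = 0.0512), though it was in 14 of 22 alternatives, among them without vector 3 (0.0419), HMGB2 1 (0.0328) or HMGB2 3 (0.0431). Without vector 2 or HMGB2 2, 1 member fell, and without vector 1 and HMGB2 3 together, 8 fell. The highest edgeR adjusted p with a library left out was 0.0918 for mt-Nd4 and 0.0656 for mt-Atp6, both without vector 2.

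Pentose phosphate and one-carbon genes held more members that fell than rose. Of 9 pentose phosphate genes, 1 rose (G6pdx, the entry enzyme, 1.33-fold) and 3 fell (Taldo1, Tkt and Pgd), and adjusted over the list alone 2 rose and 3 fell (camera adjusted p = 0.513). Without vector 3, HMGB2 1 or HMGB2 2, 1 of them fell, and the highest edgeR adjusted p with a library left out was 0.121 for Tkt (without HMGB2 1) and 0.134 for Pgd (without HMGB2 2). Of 21 genes of serine, one-carbon and nucleotide synthesis, 1 rose and 8 fell (1 and 10 adjusted over the list alone), led by the purine synthesis enzyme Atic (log2 fold change -0.72, 123 ± 8.67 to 74.7 ± 6.51 CPM) and the serine synthesis enzyme Psat1 (-0.53). This list was called downward (camera adjusted p = 0.0121; adjusted p = 0.323 with an estimated correlation), and 3 members fell without HMGB2 1 and 5 without HMGB2 2, while 0 rose without any 1 library but vector 1. Of 19 genes of cholesterol and fatty acid synthesis, 0 rose and 5 fell (7 adjusted over the list alone; camera adjusted p = 0.0899), among them Scd2 by 0.26 on the log2 scale. The list was called downward in 9 of 22 alternatives, among them fry (0.00113), and 4 members rose and 10 fell without vector 1 and HMGB2 3 together, but 0 fell without vector 2, HMGB2 1 or HMGB2 2, 1 without vector 3 and 2 without HMGB2 3. The highest edgeR adjusted p with a library left out was 0.0822 for Scd2, without HMGB2 1.

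Calcium handling and ion channel genes of cardiomyocytes rose strongly. Of 21 such genes, 17 rose, 0 fell and 4 did not pass the threshold (21 rose adjusted over the list alone), with a median fold of 1.75. Atp2a2, the calcium pump of the sarcoplasmic reticulum (ENSMUSG00000029467, GRCm38 chromosome 5, 122453513 to 122502225), rose 2.74-fold from 983 ± 27.9 to 2697 ± 93.7 CPM (edgeR adjusted p = 1.6e-06). Its regulator Pln rose 2.71-fold, the gap junction gene Gja5 3.16-fold and the potassium channel gene Kcnh2 2.87-fold, all with the 3 HMGB2 libraries above the 3 vector libraries. The exons of Atp2a2, Pln and Gja5 overlap those of tested genes on the other strand. This list was called with the preset correlation (camera adjusted p = 2.18e-25) and with an estimated one (adjusted p = 0.0411). Markers of macrophages, endothelial cells, fibroblasts, epicardial cells and smooth muscle had list medians of -0.58, -0.19, -0.10, -0.04 and -0.02. The 5 tested markers of Schwann cells and neurons had a median of 0.24.

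Of 20 sarcomere genes, 12 rose, 2 fell and 6 did not pass (15 and 2 adjusted over the list alone), with a median fold of 1.38 (camera adjusted p = 2.53e-05; adjusted p = 0.0598 with an estimated correlation). Cardiac actin, Actc1 (ENSMUSG00000068614, GRCm38 chromosome 2, 114047282 to 114053548), rose 2.64-fold from 2328 ± 164 to 6137 ± 253 CPM, Mybpc3 1.97-fold, Ldb3 1.81-fold and Actn2 1.6-fold. The members that fell, Cryab and Csrp3 (log2 fold changes -0.68 and -0.43), were named after their values were seen. They encode a small heat shock protein and a stretch-responsive protein of the Z-disc, and 1 member fell without HMGB2 1 or HMGB2 2. Of 15 fetal and stress-associated cardiac genes, 6 rose and 5 fell (6 and 6 adjusted over the list alone), with Ankrd1 and Tnni1 1.89- and 1.96-fold higher and Runx1 lower by 1.48 on the log2 scale, beside Xirp2. The list had a median of 0.04 and a mean of -0.10, and was not called (camera adjusted p = 0.797).

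**Figure D2:**
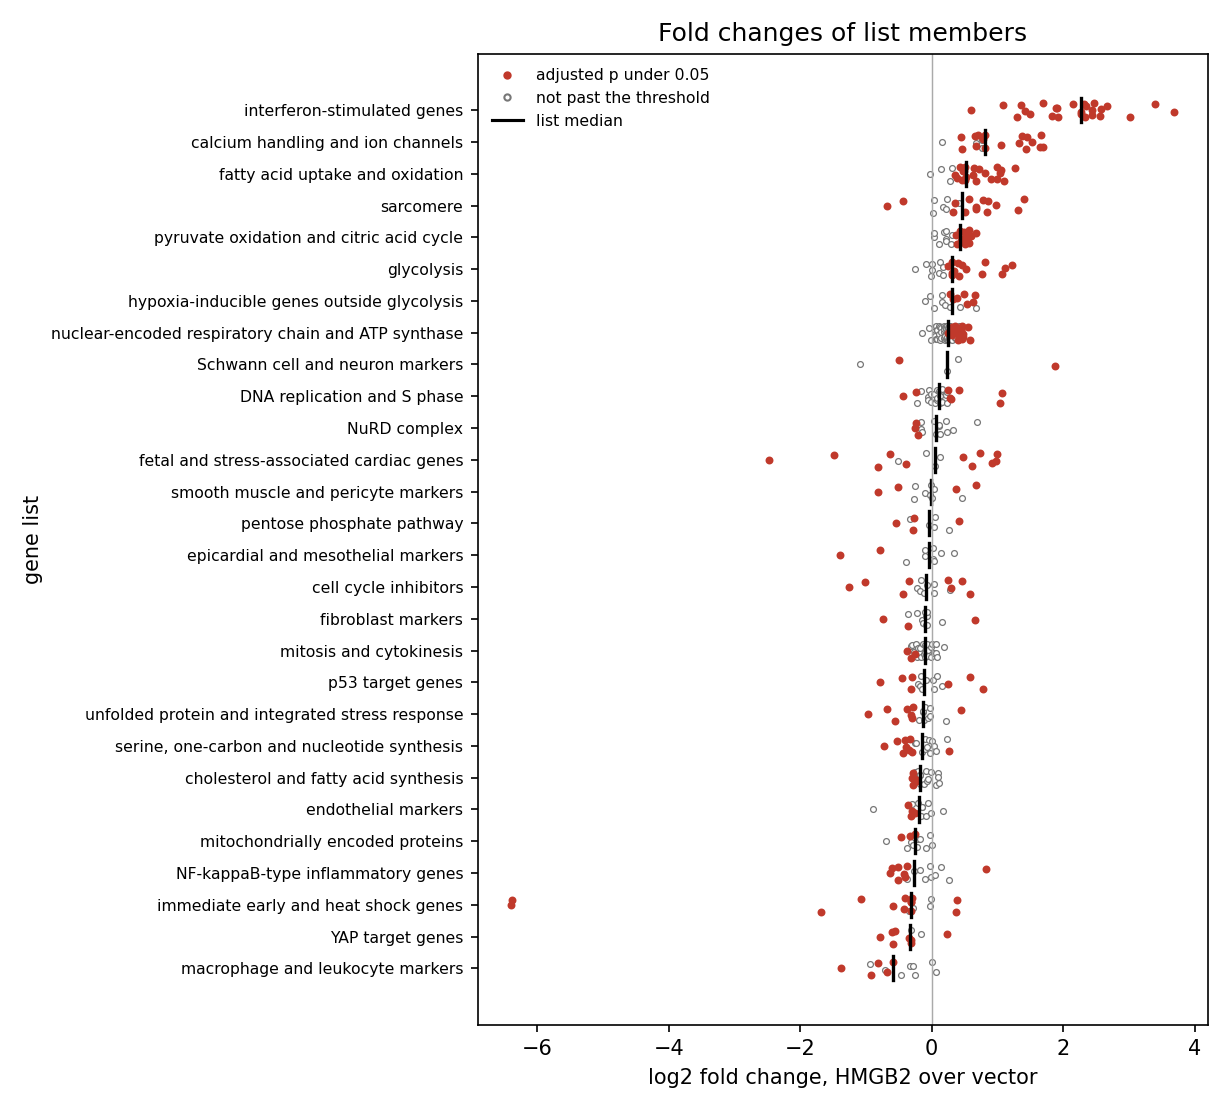
Log2 fold change of HMGB2 over vector for each tested member of 28 gene lists, with filled points for genes past an edgeR adjusted p of 0.05, open points for the others and a black line for the list median. All 26 interferon-stimulated genes lie above 0, and 2 members of the immediate early and heat shock list, Hspa1a and Hspa1b, lie below -6.

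All 26 interferon-stimulated genes rose with HMGB2, over all genes and adjusted over the list alone, by a median of 4.83-fold (log2 2.27; camera adjusted p = 1.48e-106; adjusted p = 0.0229 with an estimated correlation). Rsad2, which encodes the antiviral protein viperin, rose from 17.2 ± 1.55 to 139 ± 11.7 CPM, Ifit1 6.36-fold from 25.5 ± 3.24 to 162 ± 3.78 CPM and Ifi44 5.45-fold from 43.3 ± 5.03 to 236 ± 7.82 CPM (edgeR adjusted p between 4.59e-07 and 6.88e-07). Inflammatory genes of the NF-kappaB type did not rise with them. Of 17 such genes, 1 rose and 7 fell, over all genes and adjusted over the list alone, including Ptgs2, Nfkbiz, Icam1 and Lcn2 (log2 fold changes of -0.64, -0.60, -0.52 and -0.51). This list was called downward (camera adjusted p = 0.0234; adjusted p = 0.397 with an estimated correlation), but not without vector 1 (0.0731, with a median of -0.15 against -0.27) or HMGB2 2 (0.0642). It was higher by a median of 0.28 on the log2 scale in vector 1 and 0.15 in HMGB2 3 than in the others of their group, and 3 members fell without HMGB2 1 and 4 without HMGB2 2. The member that rose did not pass without vector 2, HMGB2 1 or HMGB2 3, and Lcn2 lost its call without HMGB2 1 (edgeR adjusted p = 0.0593) or HMGB2 2 (0.0578).

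The list of immediate early and heat shock genes was lower with HMGB2, with the largest falls in its chaperone genes. Of 17 immediate early and heat shock genes, 2 rose and 11 fell (2 and 13 adjusted over the list alone; camera adjusted p = 2.2e-23; adjusted p = 0.0598 with an estimated correlation). The median log2 fold change was -0.32 and the mean -1.07. Beside Hspa1a and Hspa1b, the chaperone genes Hsph1 (434 ± 3.86 to 136 ± 7.24 CPM, 3.20-fold lower) and Dnajb1 (110 ± 8.77 to 52.1 ± 1.87 CPM, 2.11-fold lower) had the largest falls in this list. The 13 immediate early genes outside these chaperones had a median of -0.31, with 7 lower and 2 higher, and were not tested as a list of their own. The list as a whole held 4 genes that fell without HMGB2 1 and 7 without HMGB2 2. Hspa1a, Hspa1b, Hsph1 and Dnajb1 kept their calls with any 1 library left out. They were therefore the 4 that fell without HMGB2 1, and no other immediate early gene passed downward there. In the whole list, 1 gene rose without any 1 library but vector 1. Of 17 genes of the unfolded protein and integrated stress response, 1 rose and 7 fell (1 and 8 adjusted over the list alone), with Atf3, Asns, Trib3 and Hyou1 lower by 0.96, 0.67, 0.56 and 0.31 on the log2 scale. That list was called downward (camera adjusted p = 0.0172; adjusted p = 0.663 with an estimated correlation), but not without vector 1 (0.0855, with a median of -0.06 against -0.14) or with fry (0.0943). It was higher by a median of 0.22 on the log2 scale in vector 1 and 0.15 in HMGB2 3 than in the others of their group, and 4 members fell without HMGB2 1 or HMGB2 2.

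YAP target genes, which respond to cell stretch and growth signals, were mostly lower. Of 10, 1 rose and 7 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.000703; adjusted p = 0.23 with an estimated correlation). Ccn1 went from 624 ± 47.6 to 363 ± 14.9 CPM and Ccn2 from 1233 ± 125 to 820 ± 56.4 CPM (log2 fold changes -0.78 and -0.59), and Crim1 and Amotl2 fell by 0.60 and 0.56. Without vector 2, vector 3, HMGB2 1 or HMGB2 2, 0 YAP targets rose. Of 16 hypoxia-inducible genes outside glycolysis, 7 rose and 0 fell (8 adjusted over the list alone; camera adjusted p = 0.0145; adjusted p = 0.321 with an estimated correlation), with Mxi1, Ndrg1 and Vegfa 1.54-, 1.45- and 1.41-fold higher.

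Markers of other cells of the heart were measured in both groups at levels that differed widely. The endothelial transcript Eng had 1460 ± 92.3 CPM with the vector and 1176 ± 70.2 CPM with HMGB2, and the fibroblast transcript Dcn 968 ± 65.2 and 757 ± 63.2 CPM, while the macrophage transcript C1qa had 2.04 and 0.781 CPM. Of 14 endothelial markers, 0 rose and 4 fell, over all genes and adjusted over the list alone (median log2 fold change -0.19; camera adjusted p = 0.0573). The list was called downward in 11 of 22 alternatives, among them fry (0.00454) and leaving out vector 1 (0.0463), and 10 members fell and 1 rose without vector 1 and HMGB2 3 together, while 0 fell without vector 2 or HMGB2 2, 1 without vector 3 and 2 without HMGB2 1 or HMGB2 3. The highest edgeR adjusted p with a library left out was 0.0713 for Eng (without vector 3) and 0.0771 for Dcn (without HMGB2 1). Of 14 fibroblast markers, 1 rose and 2 fell (1 and 3 adjusted over the list alone; median -0.10; camera adjusted p = 0.138), with Lum lower by 0.75, and 4 fell without vector 1 and 1 without HMGB2 1 or HMGB2 2. The fibroblast list was called downward in 5 of 22 alternatives, among them fry (0.00293), and 8 members fell without vector 1 and HMGB2 3 together and 10 with a surrogate variable. Of 13 macrophage and leukocyte markers, 0 rose and 5 fell, over all genes and adjusted over the list alone, with a median of -0.58 (camera adjusted p = 0.0121; adjusted p = 0.321 with an estimated correlation). Lyz2 had 72.5 ± 16.2 CPM with the vector and 48.3 ± 3.19 CPM with HMGB2, and its call was lost without vector 2 (edgeR adjusted p = 0.0643) or HMGB2 2 (0.0579). Without vector 2, 1 macrophage marker fell, without vector 3, HMGB2 1 or HMGB2 3, 3 fell, and the list was not called without vector 1 and HMGB2 3 together (camera adjusted p = 0.172) or with a surrogate variable (0.117). Its members had medians of -0.11 in vector 1 and -0.31 in HMGB2 3 relative to the others of their group.

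Of 12 smooth muscle and pericyte markers, 2 rose and 2 fell (camera adjusted p = 0.736), with Cnn1 1.6-fold higher and Kcnj8 lower by 0.82 on the log2 scale. Of 10 epicardial markers, 0 rose and 2 fell (camera adjusted p = 0.135; adjusted p = 0.00293 with fry), namely Krt19 (61.4 ± 6.99 to 23.3 ± 1.83 CPM) and Aldh1a2. Of 5 Schwann cell and neuron markers tested, 1 rose and 1 fell (camera adjusted p = 0.924), and this list had a median of 0.24 while the direction of its test was down. These 3 lists gave the same counts adjusted over the list alone. Of the smooth muscle markers, 1 rose without vector 2, vector 3, HMGB2 1 or HMGB2 2, and 4 fell without vector 1. Of the epicardial markers 1 rose without vector 1, and 0 of the Schwann cell and neuron markers fell without vector 2, HMGB2 2 or HMGB2 3. Erythroid markers had too few counts to be tested.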

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

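The alternatives that leave out vector 1 and HMGB2 3 together, add a surrogate variable, or correct for length and GC content were chosen after the data were seen. No named gene or list that was called, in the first test or in the alternative, changed direction under any alternative. No gene called in an alternative and in the edgeR test had opposite signs. Lists that were not called could change direction. The NuRD, the fetal and stress-associated, and the Schwann cell and neuron lists were down with camera and up with fry. Hmgb2 stayed between 2.01 and 2.2 on the log2 scale. Of 121 named genes past the threshold, 83 kept their calls under every alternative and 38 lost them under at least 1. Of all calls 57.2% were upward, against 67.4% with FPKM and no filter, 64.4% without HMGB2 1, 62.0% with library totals only, 52.2% without vector 1 and HMGB2 3, 51.2% with a surrogate variable and 50.5% with the length and GC correction.

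The number of genes higher and lower was 1387 and 671 with FPKM and no filter, 743 and 166 at a log2 fold change of at least 1, 1303 and 551 against a fold of 1.2, and 3794 and 3622 with a surrogate variable. It was 3265 and 2986 without vector 1 and HMGB2 3, and 2812 and 2752 with the length and GC correction. With each library left out in turn, 1567 to 2526 genes were higher and 866 (without HMGB2 1) to 1960 (without vector 1) lower. With 5 libraries fewer samples enter the fit, and otherwise the cause was not tested.

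Deviations from the group mean had correlations of -0.32, 0.23 and -0.37 between samples with the same replicate number, which gives no sign of a pairing. They cannot exclude one, because the deviation shared by vector 1 and HMGB2 3 (correlation 0.52) could mask it. With the replicate number as a block, 1459 genes were higher and 754 lower (65.9% upward), and the mitochondrially encoded list had a camera adjusted p of 0.0433.

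With an estimated correlation the camera adjusted p was 0.268 for glycolysis, 0.112 for fatty acid oxidation, 0.379 for the citric acid cycle and 0.772 for the respiratory chain. With fry it was 0.0346 for S phase, 0.00676 for mitosis, 0.197 for the respiratory chain and 0.00975 for the mitochondrially encoded genes. The camera adjusted p of S phase was 0.0375 with no filter and 0.037, 0.0386 and 0.00195 with FPKM (pseudocounts 1 and 0.1, and 1 with no filter). That of mitosis was 0.0323 with no filter, 0.0177 with voom and 0.0364, 0.0354 and 0.0088 with FPKM. That of the mitochondrially encoded genes was 0.0493 with size factors of the DESeq2 type, 0.0107 with no filter, 0.0259 with DESeq2, 0.00463 with voom, 0.00871, 0.00991 and 0.000827 with FPKM, 0.0252 without vector 1 and HMGB2 3, and 0.0183 with a surrogate variable. With each library left out it ranged from 0.0459 (without vector 3) to 0.109 (without vector 1) for mitosis, from 7.21e-09 (without vector 1) to 0.0709 (without HMGB2 3) for the respiratory chain, and from 0.0328 (without HMGB2 1) to 0.0858 (without HMGB2 2) for the mitochondrially encoded genes. The cause of these differences was not tested.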

Other observations

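The gene groups in this paragraph and the next were chosen after the data were seen, as were the tests of near-identical copies, of handling shared by the vector cultures and of leukocytes further below. Of 22 chaperone genes, among them Hspa1a, Hspa1b, Hsph1 and Dnajb1 of the fixed immediate early and heat shock list, 19 fell and 0 rose with HMGB2 (edgeR, adjusted p under 0.05). Hspa8, the constitutive member of the HSP70 family, had 1623 CPM with the vector and 406 CPM with HMGB2 (log2 fold change -2.00, SE 0.08). Hsp90aa1 had 1563 and 565 CPM, the mitochondrial chaperonin gene Hspd1 851 and 296 CPM, and the small heat shock protein gene Hspb1 283 and 105 CPM. Of 12 antioxidant genes of the NRF2 type, 8 fell and 1 rose, with Txnrd1, which encodes a thioredoxin reductase, at 854 and 283 CPM and Nqo1 as the member that rose (log2 fold change 0.44, SE 0.09).

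Among genes outside the fixed interferon list, all 12 genes of MHC class I antigen presentation tested rose (edgeR, adjusted p under 0.05), with a median log2 fold change of 0.95, from B2m (1.73-fold, 518 to 896 CPM) to its transcriptional activator Nlrc5 (3.55-fold, 6.36 to 22.7 CPM). All 12 interferon-inducible GTPases rose, with a median of 1.79 and Igtp 5.74-fold higher. Of 11 genes of nucleic acid sensing, 8 rose, of which Ifih1, Zbp1 and Ddx58 are in the fixed interferon list and Dhx58 (3.36-fold) and Tlr3 (2.48-fold) are not, while Cgas, Aim2 and Mavs had log2 fold changes of 0.24, 0.17 and 0.25 that did not pass the threshold.

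The lower chaperone transcripts were weighed against 3 technical explanations. For 6 chaperones with a near-identical copy over at least 50% of the transcript, the counts of the copies were added. Their median log2 fold change stayed at -1.754, and the highest of them was -1.439. Hspa1a and Hspa1b are copies of each other, so the same sum (-6.401) entered this median for both. That all of these sums fell argues against reads moved between these copies. Shorter copies, such as those of Dnaja1 and Hspe1, were not added. Reads left uncounted because they match several genes are not covered, since their handling is not given. In Hspa1b the gap between the lowest vector and the highest HMGB2 library was 6.336 log2 units. Hspa1b was named among genes with fully separated groups, so a gap was given by that choice. It is therefore no independent test of stress in a single vector culture. The labels also do not say whether the vector libraries come from separate cultures. The chaperone median was higher in 3 of 3 vector libraries than in every HMGB2 library, which handling stress shared by the vector cultures and an effect of HMGB2 would both give, so these cannot be told apart without a record of the handling. An effect of HMGB2 on the heat shock response may therefore be considered only as a hypothesis.

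The interferon response was weighed in the same way. More macrophages in the HMGB2 cultures are argued against by the macrophage and leukocyte list, whose median log2 fold change was -0.5836 with 0 members higher. The fall of the list was not called without vector 1 and HMGB2 3 together (median -0.368) or with a surrogate variable (median -0.566), though 0 members rose there too. The list holds mostly macrophage markers, some with few counts, so other leukocytes are hardly covered by it. A trend with GC content or gene length is argued against by the interferon median of 2.246 after correction for both. A different amount of virus in the groups may also raise interferon-stimulated genes, and it cannot be told apart from an effect of HMGB2, because 0 counted rows have an identifier other than a mouse Ensembl gene and viral transcripts were not analysed here.

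The higher cardiomyocyte genes could come from a larger share of cardiomyocytes in the HMGB2 cultures. As the sole cause this is argued against by the sarcomere genes, of which 13 of 20 lay over 2 SE from the list median. Their log2 fold changes ran from -0.68 (Cryab) to 1.40 (Actc1). A change in share alone would move genes expressed only in cardiomyocytes by 1 factor. Whether all members are such genes was not tested. The spread of members does not measure a shift common to all of them. A contribution from cell share, of unknown size, therefore stays open. This holds also for fatty acid oxidation, the citric acid cycle and glycolysis (medians of 0.52, 0.43 and 0.31, against 0.46 for the sarcomere list). A smaller share of other cells could likewise lower genes expressed mainly in them. Whether this contributes to lists that fell, such as the YAP targets and the inflammatory genes, was not tested. Markers of macrophages, endothelial cells and fibroblasts had medians of -0.58, -0.19 and -0.10, the direction that a larger share of cardiomyocytes would give. Those of epicardial cells and smooth muscle lay at -0.04 and -0.02, and those of Schwann cells and neurons at 0.24. A trend with GC content or gene length is argued against by the calcium handling median of 0.7772 after correction, and an effect of HMGB2 on these genes stays a hypothesis.

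Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the real one, which is the real split itself, with 3886 genes, and the highest other split gave 0. Every other split puts vector and HMGB2 libraries in the same group, so a difference between them widens the spread within groups. Few calls could come from such splits, and their number is no measure of chance. With 10 splits the share cannot fall under 0.05.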
